A study of Mus musculus with 44 samples.

How the data were processed

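Total RNA of the mouse cochlear nucleus was measured on Affymetrix arrays after removal of 1 cochlea at P7 or P21. Per the labels, the nucleus was dissected fresh and snap frozen, RNA was extracted with a lipid tissue kit and DNase treatment on the column, and it was labelled with biotin by the manufacturer's protocol. The 44 arrays fall into 16 groups by age (P7 or P21), time after surgery (6, 12, 24 or 48 h) and side (deafferented, or the control nucleus opposite), with 2 arrays per group at 6 h and 3 per group at 12, 24 and 48 h. According to the series design, each replicate was a separate pool of tissue. The p-values therefore describe the spread between pools, and the number of animals per pool is not given in the sources used here. Group and replicate number of each array were taken from its labels.

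The authors deposited one table of log2 expression values per probe set, made with GCRMA per the submitters' processing notes, of which no version is given in the sources used here. Whether all arrays were normalised together is likewise not given. The deposited log2 values were used without further normalisation. The 44 arrays have medians between 5.962 and 6.164, 5th percentiles between 2.12 and 2.486, and between 59.3% and 61.88% of their probe sets above log2 5, the level used here as the limit of background signal. Arrays of one group correlated with r between 0.943 and 0.9926.

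Probe sets were paired with genes through the table of probe sets and genes supplied with the data: of 22626 probe sets, 20380 had 1 symbol, 691 had several and 1555 stayed unnamed here, and 20351 of those with 1 symbol were matched by gene identifier to the reference table of assembly GRCm38.p6. No coordinates were used. Probe sets with a value above log2 5 in at least 2 arrays were kept, which left 15323, of which 1226 had several symbols or none. For gene lists and named genes, each of 8886 genes was represented by its kept probe set with the highest mean over all arrays.

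The comparisons were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, contrasts between groups, and moderated variances with a trend on the mean (28 residual and 5.27 prior degrees of freedom). The 18 contrasts were deafferented minus control at each age and time, the mean of these over the 4 times at each age, the mean effect at 24 and 48 h minus that at 6 and 12 h at each age, the P21 effect minus the P7 effect at each time and averaged, and P21 minus P7 controls averaged over the times. P-values are two-sided and adjusted by the Benjamini-Hochberg method within a contrast, and a probe set was called at an adjusted p under 0.05. The SE given with a log2 change is that of limma's fit, and a fold is 2 to the power of that change.

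Gene lists, 37 in number, were written from textbook knowledge for cell types, injury and immune responses, neuronal function and cell biology. Each with at least 5 measured genes was tested against all other genes with limma's camera, with a preset correlation between genes of 0.01 and the Benjamini-Hochberg adjustment over the lists. The preset correlation makes this test lenient, so each call is also given with a correlation estimated per list. In the text, "adjusted over the list alone" means that only the genes of that list entered the adjustment.

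Genes were named by a fixed rule among probe sets with 1 symbol, 1 per gene. For the averages at each age these were the 10 largest increases and decreases past the threshold with the same sign at all 4 times. For each age and time, and for the contrasts of late with early times and of the ages, they were the 5 largest of each sign past the threshold, and for the control ages the 10 largest of each sign. Up to 4 members with the smallest adjusted p were named for a described list, and 10 further genes are reported whatever their values for the averages, for each age and time (as a range where none passed), for the averaged age difference and for the control ages, with 2 more of that kind not reported here. The groups, contrasts, tests, thresholds, gene lists, naming rule and all alternatives except 3 were chosen before the data were examined. The exceptions, chosen after the data were seen, are leaving out the replicate 3 arrays of 12 and 48 h, leaving out the 24 h arrays, and combining the pair block with an estimated correlation. The list tests at single times were also added then.

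Whether arrays with the same number on both sides form pairs was tested by correlating their deviations from their group means across probe sets. The lowest such correlation in an age and time was above the limit of 0.1, set beforehand, for P7 12 h (0.353), P7 48 h (0.23), P21 12 h (0.312), P21 24 h (0.158) and P21 48 h (0.428), and not for P7 6 h (0.0704), P7 24 h (-0.00178) and P21 6 h (0.0642). A fit with the pair as a block (14 residual degrees of freedom) was therefore run as an alternative and its counts are given beside the results. These correlations do not by themselves show pairs, since the replicate 3 arrays of 12 and 48 h stood apart on both sides. Low ones do not show that pairs are absent either. At 6 h, with 2 arrays per side, the correlation with the other number is fixed as the same value with its sign turned. Some arrays correlated more with another number than with their own. Where the limit was passed, these were P21 12 h replicates 1 (0.312 against 0.493) and 2 (0.324 against 0.506), and P7 48 h replicate 2 (0.23 against 0.493). The number of pairs that moved in the stated direction is given beside adjusted p values as a description.

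The other alternatives were no filter on dim probe sets, a filter at log2 7 (10802 probe sets), quantile normalisation, centring arrays on their medians, robust moderation, a constant variance prior, array weights, fitting each age or each pair of groups alone, a random block, a minimum of 1.5-fold, 1 probe set per gene, the mean of a gene's probe sets, limma's fry (which tests a list against no change, not against the other genes), and leaving out each array in turn. Where leaving out an array left a group with 1, that array was assumed to vary like the others. The steps were tested on simulated data, in which 67 probe sets were changed by log2 0.5, 67 by log2 1 and 66 by log2 2. For the P21 average, 61.2% of changes of log2 0.5 and 98.5% of changes of log2 1 were recovered, for P21 at 48 h 11.9% and 76.1%, and for the averaged age difference 44.8% and 82.1%. False calls were 4.42%, 3.91% and 3.82% of all calls in these 3 comparisons. The simulated noise was independent between probe sets and between arrays, without pairs or replicate 3 arrays that stand apart. These rates therefore need not hold for the real arrays. Each contrast was also recomputed for other splits of the same arrays, with 10 splits for 3 arrays against 3 and 100 otherwise. Permutation p-values were computed in R 4.3.3, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.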

Results

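The cochlear nucleus is the first station of the auditory pathway in the brainstem and receives the axons of the auditory nerve. Mice had 1 cochlea removed at postnatal day 7 (P7) or postnatal day 21 (P21), which took away the nerve input to the cochlear nucleus of the same side. RNA from the deafferented nucleus and from the nucleus of the opposite side, the control, was measured on Affymetrix arrays 6, 12, 24 and 48 h after surgery. No group came from animals without surgery. A rise or fall given here is therefore relative to the opposite nucleus, and the change may lie in either nucleus. The 16 groups of age, time and side held 2 arrays each at 6 h and 3 arrays each at 12, 24 and 48 h, 44 arrays in all, each from its own pool of tissue according to the series design. Each array gave log2 expression values for 22626 probe sets. The median value of an array lay between 5.962 and 6.164, and the correlation between 2 arrays of one group lay between 0.943 and 0.9926. The replicate 3 arrays of 12 and 48 h stood apart from the others on both sides and at both ages. The 5th percentile of their values averaged 2.432 ± 0.0501 (SD, n = 8 arrays), against 2.218 ± 0.0537 (n = 16) for replicates 1 and 2 of those times. The number of arrays limits the precision of every value given here.

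The first comparison asked which genes differed between the deafferented and the control nucleus of animals operated on at P21, as a mean over the 4 times. Genes of reactive astrocytes and of microglia rose, and several immediate early genes fell. Timp1, an inhibitor of matrix metalloproteinases that reactive astrocytes release, rose 3.35-fold (log2 change 1.74 ± 0.257 SE, 11 arrays per side, limma adjusted p = 6.03e-05, higher in 10 of 11 pairs of arrays with the same number). Cd68, a lysosomal protein of microglia and macrophages, rose 3.1-fold (1.63 ± 0.238, adjusted p = 5.27e-05, 10 of 11 pairs). Gadd45a, a stress-induced gene of growth arrest and DNA damage, rose 2.65-fold (1.41 ± 0.118, adjusted p = 2.33e-09, 11 of 11 pairs), from a log2 level of 7.67 ± 0.33 (SD, n = 11) in the controls to 9.07 ± 0.38. Fos, the immediate early gene, fell by 1.23 on the log2 scale (± 0.148, adjusted p = 2.19e-06, lower in 11 of 11 pairs).

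Of the other genes named for the size of their increase at P21, Ccl12, a chemokine, rose by 1.57 (adjusted p = 0.000183, higher in 10 of 11 pairs). Serpina3n, a protease inhibitor of reactive astrocytes, rose by 1.54 (adjusted p = 0.000776, 11 of 11). Lgals3, a galectin of activated microglia, rose by 1.46 (adjusted p = 2.53e-05, 11 of 11), and Socs3, a feedback inhibitor of cytokine signalling, by 1.42 (adjusted p = 2.13e-05, 11 of 11). Cd44, a hyaluronan receptor, rose by 1.12 (adjusted p = 3.59e-06, 11 of 11), and Lcn2, an iron-binding acute-phase protein, by 1.10 (adjusted p = 0.00561, 11 of 11). Lalba, a milk protein, rose by 1.38 (adjusted p = 6.7e-07, 9 of 11). Among the decreases were Arhgap24 (-1.01, adjusted p = 2.02e-07), Dusp1, a phosphatase that ends MAP kinase signalling (-0.81, adjusted p = 2.02e-07), and Rgs2 (-0.81, adjusted p = 2.13e-05). Nr4a1, an immediate early nuclear receptor, fell by 0.82 (adjusted p = 0.000326). Also lower were the neuropeptide genes Adcyap1 (-0.82, adjusted p = 0.000286) and Cck (-0.65, adjusted p = 0.000174), the activin subunit Inhbb (-0.74, adjusted p = 0.0101) and C1ql3 (-0.63, adjusted p = 0.00137). Tnnt1, a troponin, fell by 0.78 (adjusted p = 0.00053). Each of these decreases was seen in 11 of 11 pairs, except those of Nr4a1 and Adcyap1 in 10 of 11. Control means at P21 lay below log2 5, near the background of the arrays, for Timp1 (4.41), Cd68 (4.91), Ccl12 (2.68 ± 0.26) and Lalba (2.41), so the size of their changes rests on low control values. The deafferented means of Ccl12 (4.24) and Lalba (3.9) lay below log2 5 as well.

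The genes followed whatever their values gave a mixed picture at P21. Jun, an immediate early gene of axon injury, rose by 0.75 ± 0.091 (limma adjusted p = 2.49e-06), and Atf3, a transcription factor induced by nerve injury, by 1.03 ± 0.155 (adjusted p = 8.06e-05). C1qa, a subunit of the complement protein C1q, rose by 0.64 ± 0.105 (adjusted p = 0.000324). Each of the 3 was higher in 11 of 11 pairs. Gfap, the intermediate filament of astrocytes, differed by 0.73 ± 0.292 and did not pass (adjusted p = 0.515), although it was higher in 10 of 11 pairs. Its level was lower in the replicate 3 arrays of 12 and 48 h, averaging 8.94 ± 0.53 (SD, n = 8), than in replicates 1 and 2 of those times (10.51 ± 0.43, n = 16). With the pair as a block its adjusted p was 4.55e-05 (4.55e-05 to 1 over its alternatives). Gap43, a protein of growing axons, differed by 0.60 ± 0.183 (adjusted p = 0.176, with the block 0.0335, 0.000174 to 1 over all alternatives). Igf1, a growth factor, differed by 0.29 ± 0.103 (adjusted p = 0.353), the survival gene Bcl2 by -0.45 ± 0.135 (adjusted p = 0.158) and the calcium-binding protein Calb2 by -0.19 (adjusted p = 0.946), and none of the 3 passed.

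In all, 124 of 15323 probe sets (95 genes) passed limma's test at P21 averaged over the times, 79 higher and 45 lower on the deafferented side. With the array pair as a block, 286 passed, 162 higher and 124 lower. Without the 24 h arrays, an alternative chosen after the data were seen, 35 passed, 17 higher and 18 lower, and 13 of the genes named above lost their call. Of these, Ccl12 and Lalba fell below the filter on dim probe sets without those arrays and had no value. The other 11 were Socs3 (adjusted p = 0.066), Cd68 (0.076), C1ql3 (0.105), Cck (0.125), Cd44 (0.17), Nr4a1 (0.17), Timp1 (0.253), Serpina3n (0.253), Lcn2 (0.266), Inhbb (0.4) and Atf3 (0.504). Each value is the highest adjusted p of that gene's alternatives, of which the lowest lay between 3.82e-09 for Cd44 and 0.000187 for Lcn2.

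Grouped by the gene lists fixed in advance, the reactive astrocyte list stood out at P21, with a median log2 change of 0.55 over 27 measured genes. Of these 27 genes, 13 rose and 0 fell (19 rose when adjusted over the list alone), led by Tgm1, a transglutaminase (0.90, adjusted p = 2.37e-06), Cd44, Socs3 and Lgals3. The list rose in limma's camera test (adjusted p = 2.39e-33 with the preset correlation and adjusted p = 2.18e-05 with an estimated correlation). The microglia and macrophage list had a median of 0.45 over 29 genes, of which 9 rose (18 when adjusted over the list alone). Among them were Ly86 (0.85, adjusted p = 2.13e-05) and the signalling adaptor Tyrobp (0.73, adjusted p = 0.000455). The list rose (adjusted p = 5.53e-30, and adjusted p = 0.000127 with an estimated correlation). The complement list (median 0.27, 8 genes, 1 called higher, 4 when adjusted over the list alone) rose with adjusted p = 8.53e-07 and adjusted p = 0.000363 with an estimated correlation. The cytokine and chemokine list (median 0.07, mean 0.25, 16 genes, 2 called higher, 5 when adjusted over the list alone) rose with adjusted p = 2.31e-05 and adjusted p = 0.000363 with an estimated correlation. Its called members were Ccl3 at 0.98 (adjusted p = 0.000105) and Ccl12. Some genes are in more than 1 list, so list calls are not fully separate results. Genes also in another list were 7 of 27 for reactive astrocytes and 3 of 29 for microglia and macrophages. They were 3 of 8 for complement and 1 of 16 for cytokines and chemokines.

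Lists that fell at P21 were led by the meninges and choroid plexus list, marker genes of the tissues that border the cochlear nucleus. Its median was -0.36 over 22 genes, 21 of them with a fitted change below 0, of which Col1a2 passed (-0.41, adjusted p = 0.0292) and 9 when adjusted over the list alone. The list fell with adjusted p = 8.96e-13, and with adjusted p = 0.0179 with an estimated correlation. Levels of the 4 choroid plexus genes Ttr, Kl, Folr1 and Kcne2 were uneven between arrays of one group, as their plot by array shows. The immediate early gene list had a median of -0.16 over 16 genes: Fos, Nr4a1 and Dusp1 fell and Jun rose, with 5 lower and 1 higher when adjusted over the list alone. This list fell with adjusted p = 0.00161, and with adjusted p = 0.0351 with an estimated correlation, but not with the array pair as a block as well (adjusted p = 0.129, 0.000411 to 0.129 over its alternatives).

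The calls of 7 other lists at P21 held with the preset correlation but were lost with an estimated one. The cytosolic ribosomal protein list lay slightly above 0 (median 0.08, fitted changes above 0 for 40 of 40 genes, 0 called, adjusted p = 2.08e-08, and adjusted p = 0.241 with an estimated correlation). For axon injury and growth the median was -0.01 and the mean 0.12, with the test's direction upward (adjusted p = 0.00466, and adjusted p = 0.0542 with an estimated correlation). Of its 32 genes 3 were called higher, Gadd45a, Atf3 and Hspb1, a small heat shock protein (0.47, adjusted p = 0.0433), and the neuropeptide gene Adcyap1 lower. Extracellular matrix and proteases had a median of 0.03 (adjusted p = 0.00477, and adjusted p = 0.208 with an estimated correlation). The endothelium and pericyte list had a median of -0.11, with Kcnj8 called lower at -0.41 (adjusted p = 0.000848, and adjusted p = 0.159 with an estimated correlation). Medians were -0.05 for the mitochondrial respiratory chain (adjusted p = 0.0111, and adjusted p = 0.663 with an estimated correlation) and -0.08 for synaptic vesicles and release (adjusted p = 0.0391, and adjusted p = 0.663 with an estimated correlation). Oligodendrocytes and myelin had a median of 0.06 (adjusted p = 0.0466, and adjusted p = 0.757 with an estimated correlation). In total 13 of 37 lists were called at P21, 8 up and 5 down, and 6 of these 13 calls held with the estimated correlation.

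**Figure D1:**
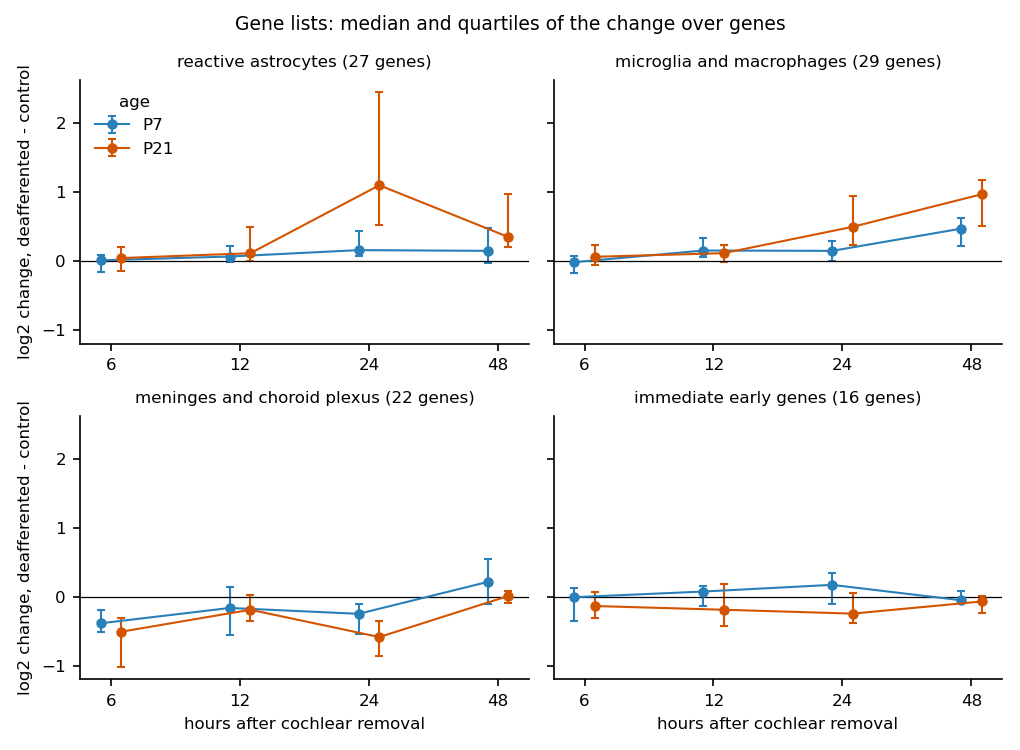
Median log2 change (deafferented minus control) of 4 gene lists against hours after cochlear removal at P7 and P21, where the vertical lines span the quartiles of each list's genes. At P21 the reactive astrocyte list peaked at 24 h with a median of 1.10, and the microglia list was highest at 48 h with 0.97.

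At single times after removal at P21, the number of called probe sets was 0 at 6 h, 4 at 12 h, 124 at 24 h and 54 at 48 h. At 6 h no probe set passed limma's test (177 at an unadjusted p under 0.05, and 3 with the array pair as a block). The smallest adjusted p was that of Gadd45a, with a change of 1.48 ± 0.273 (adjusted p = 0.0774, higher in 2 of 2 pairs), and Fos differed by -1.62 ± 0.341 (adjusted p = 0.144, 1.61e-06 to 0.179 over its alternatives). The other 9 genes followed whatever their values lay between -0.34 (Bcl2) and 0.47 (Jun) at 6 h, each with adjusted p = 1. At 12 h, Ccl3, a chemokine that attracts macrophages, rose 5.22-fold (2.39 ± 0.284, n = 3 arrays per side, limma adjusted p = 1.51e-05), from a log2 level of 3.05 ± 0.04 (SD) near the background to 5.44 ± 0.61. Gadd45a rose by 1.18 ± 0.223 (adjusted p = 0.0399) and Lpl, a lipase that microglia produce, by 1.14 ± 0.21 (adjusted p = 0.0397). Adcyap1 fell by 1.30 ± 0.252 (adjusted p = 0.0443), each of the 4 in 3 of 3 pairs. With the array pair as a block, Adcyap1 had an adjusted p of 0.122, within 0.00578 to 0.999 over its alternatives. The calls of Gadd45a and Lpl ended without 5 of the 6 arrays and that of Adcyap1 without each of the 6, with adjusted p up to 0.592 (without control replicate 3). The count was 1 without control replicate 1, control replicate 3, deafferented replicate 1 or deafferented replicate 2, and 2 without deafferented replicate 3. With the 2 groups of 12 h fitted alone it was 0. None of the genes followed whatever their values passed at 12 h: Jun differed by 0.70 ± 0.172 (adjusted p = 0.297, 0.000856 to 0.999 over its alternatives), and the others lay between -0.76 (Fos) and 1.14 (Cd68), each with adjusted p = 1.

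**Figure D2:**
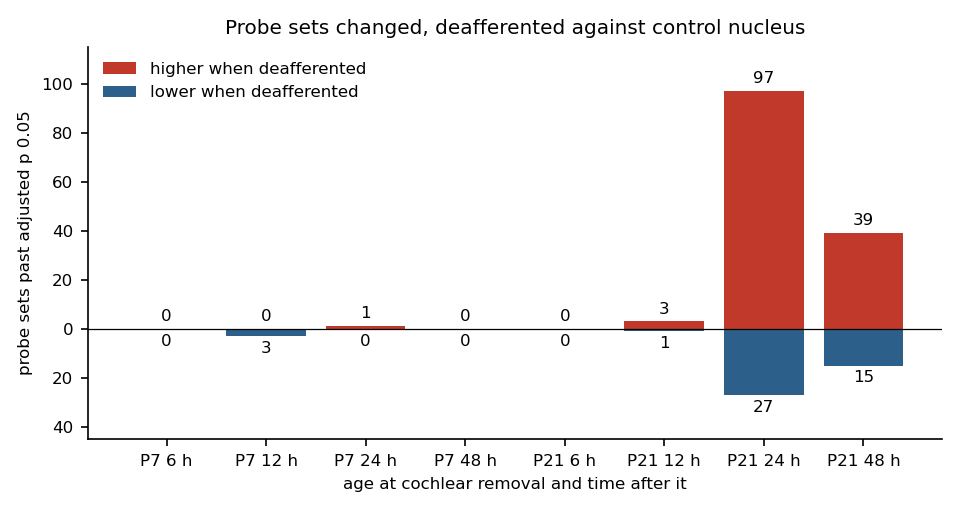
Number of probe sets with a limma adjusted p under 0.05 that were higher or lower on the deafferented side, as bars by hours after cochlear removal at P7 and P21. The bars at P21 reach 97 higher and 27 lower at 24 h, and the largest number at P7 is 3, all lower, at 12 h.

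At 24 h after removal at P21, the largest increases came from low levels in the controls. Timp1 rose 17.3-fold (4.12 ± 0.485, n = 3 arrays per side, limma adjusted p = 8.43e-07), from a log2 level of 4.45 ± 0.14 (SD) to 8.57 ± 0.63. Lalba rose 16.8-fold (4.07 ± 0.293, adjusted p = 1.63e-11) and Tgm1 9.61-fold (3.27 ± 0.207, adjusted p = 7.96e-13), both also from control means below log2 5. Serpina3n rose by 3.19 ± 0.512 (adjusted p = 0.000224), Lgals3 by 3.06 ± 0.385 (adjusted p = 2.9e-06), Cd68 by 2.66 ± 0.448 (adjusted p = 0.000446) and Atf3 by 2.36 ± 0.292 (adjusted p = 2.27e-06). Each of these 7 genes was higher in 3 of 3 pairs. Hmox1, which degrades heme, rose from a log2 level of 5.63 ± 0.14 to 8.15 ± 0.19 (2.52 ± 0.285, adjusted p = 3.34e-07). Fos fell by 1.67 ± 0.279 (adjusted p = 0.000378), from 10.07 ± 0.09 to 8.39 ± 0.08, and Nr4a1 by 1.49 ± 0.257 (adjusted p = 0.000592). Jun rose by 1.16 ± 0.172 (adjusted p = 5.6e-05). Of the other genes followed whatever their values, C1qa (0.59, adjusted p = 0.275), Bcl2 (-0.81, adjusted p = 0.195) and Calb2 (-0.36, adjusted p = 0.875) did not pass. Nor did 3 that passed with the array pair as a block: Gfap (1.34, adjusted p = 0.559, with the block 5.68e-05, 5.68e-05 to 0.731 over its alternatives), Gap43 (1.19, adjusted p = 0.126, with the block 0.0235, 0.00116 to 0.16 over its alternatives) and Igf1 (0.62, adjusted p = 0.19, with the block 0.045, 0.0143 to 0.482 over its alternatives).

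List tests at single times were added after the data were seen, and their adjusted p values are given with an estimated correlation. The reactive astrocyte list had a median of 1.10 at 24 h, with 13 of 27 genes called higher (camera adjusted p = 8.91e-07). Its members with the smallest adjusted p included Cd44 (2.69, adjusted p = 2.24e-08), the sphingosine receptor S1pr3 (2.23, adjusted p = 1.34e-07) and the pentraxin Ptx3 (2.71, adjusted p = 3.15e-07). The microglia list had a median of 0.50, with 5 of 29 genes called higher (adjusted p = 0.00412). Cytokines and chemokines had a mean of 0.46 with 4 of 16 called (adjusted p = 0.000216). The complement list had a median of 0.40 (adjusted p = 0.00416) and the unfolded protein and integrated stress response one of 0.14 (adjusted p = 0.00416). Axon injury and growth had a median of 0.06 and a mean of 0.31 with 4 of 32 called (adjusted p = 0.00416). Called members of the axon injury list were Atf3, Hspb1 (1.78), the tubulin Tubb6 (2.20) and Gadd45a (1.59).

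The meninges and choroid plexus list moved with the deafferented side at the same time, with a median of -0.59 and 2 genes called lower (adjusted p = 0.0425 with an estimated correlation). Ttr, the transthyretin of the choroid plexus, fell by 3.47 ± 0.798 (adjusted p = 0.0213), but was lower in 2 of 3 pairs. Its log2 level was 9.22 and 8.9 in deafferented replicates 2 and 3, 14.43 in replicate 1, and 13.85 to 14.72 in the controls. The highest value of any probe set in these 3 control arrays was 14.467 to 14.907, so Ttr lay at or near the top of the scale and the size of its fall is not exact. Chad, a matrix protein of cartilage (-1.22 ± 0.268, adjusted p = 0.0123), and Myl9, a myosin light chain of smooth muscle (-1.17 ± 0.241, adjusted p = 0.00669), fell as well, each in 3 of 3 pairs. The calls of these 3 genes ended without control replicate 1 (adjusted p = 0.0525 for Ttr, 0.205 for Chad and 0.13 for Myl9) and without deafferented replicate 2 (0.33, 0.179 and 0.219). Those of Ttr and Chad ended without deafferented replicate 3 (0.3 and 0.0963), and that of Ttr also without control replicate 2 (0.0843) or 3 (0.0858). The same list was lower at 6 h (median -0.51, adjusted p = 0.00451 with an estimated correlation) and not at 48 h (median 0.01, adjusted p = 0.996 with an estimated correlation).

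At 24 h, 124 probe sets (100 genes) passed limma's test, 97 higher and 27 lower, and with the array pair as a block 249 did, 176 higher and 73 lower. The count fell to 71 without control replicate 1 and to 60 without deafferented replicate 2, and to 61 with the 2 groups fitted alone.

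**Figure D3:**
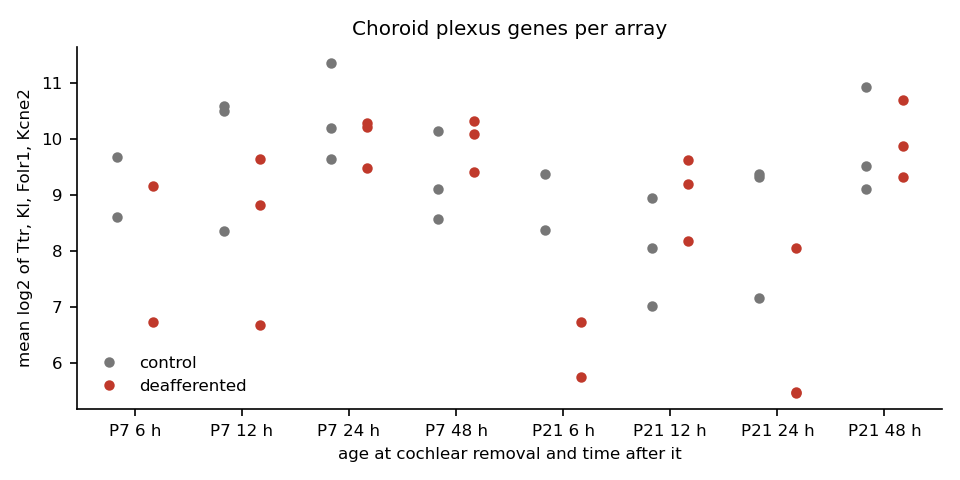
Mean log2 level of the 4 choroid plexus genes Ttr, Kl, Folr1 and Kcne2 in each array (points), by age, time and side. The lowest arrays of P21 are deafferented arrays of 24 h at 5.48 and 5.49 and of 6 h at 5.76 and 6.74.

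By 48 h after removal at P21 the microglia list showed its largest shift. Its median was 0.97, with 11 of 29 genes called higher (camera adjusted p = 1.05e-06 with an estimated correlation). Among them were Ly86 (1.54, adjusted p = 0.000283) and Mpeg1, a pore-forming protein of macrophages (1.73, adjusted p = 0.000603). Cd68 rose by 2.51 ± 0.448 (n = 3 arrays per side, limma adjusted p = 0.00255) and C1qa by 1.17 ± 0.199 (adjusted p = 0.00144). The complement list had a median of 0.41 with 3 of 8 genes called (adjusted p = 2.67e-05 with an estimated correlation), the C1q subunits C1qa, C1qb (0.97, adjusted p = 0.0181) and C1qc (1.27, adjusted p = 0.036). The reactive astrocyte list had a median of 0.35 with 2 of 27 called (adjusted p = 0.000833 with an estimated correlation). Timp1 was raised by 2.52 ± 0.485 (adjusted p = 0.00591), at 6.91 ± 1.67 (SD) against 4.40 ± 0.08. Sprr1a, a gene of regenerating axons (1.88 ± 0.277, adjusted p = 0.000312), Ecel1, a protease of injured neurons (1.82 ± 0.273, adjusted p = 0.000354), and Atf3 (1.56 ± 0.292, adjusted p = 0.00408) rose as well. Mapk13, a p38 kinase, rose 3.82-fold (1.93 ± 0.206, adjusted p = 1.14e-06). All 7 genes given here with an SE were higher in 3 of 3 pairs. Sprr1a and Ecel1 exceeded log2 5 in only 2 arrays each. They passed without each of 4 arrays, and fell below the filter and had no value without deafferented replicate 1 or 2.

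Decreases at 48 h included Tnnt1 (-1.42 ± 0.253, limma adjusted p = 0.00255), Inhbb (-1.31 ± 0.304, adjusted p = 0.0377) and Arhgap24 (-1.03 ± 0.203, adjusted p = 0.00706). C1ql3 (-1.01 ± 0.22, adjusted p = 0.023) and Cd24a, a glycoprotein of immature neurons (adjusted p = 0.00199), fell as well, and each of the 5 was lower in 3 of 3 pairs. Gap43 was at 6.82 ± 0.31 (SD) against 5.41 ± 0.23 in the controls and did not pass (adjusted p = 0.0734), but did with the array pair as a block (adjusted p = 0.0103, 0.000972 to 0.252 over all alternatives). The same held for Gfap (1.32, adjusted p = 1, with the block 0.000297, 0.000297 to 1 over its alternatives), Jun (0.65, adjusted p = 0.13, with the block 0.0444, 0.0136 to 0.979 over its alternatives) and Fos (-0.85, adjusted p = 0.49, with the block 0.0177, 0.0177 to 1 over its alternatives). Bcl2 (-0.31), Igf1 (0.18) and Calb2 (-0.03) did not pass (adjusted p = 1 for each). In all 54 probe sets (45 genes) passed, 39 higher and 15 lower, and 104 with the block, 69 higher and 35 lower. The count was 35 without control replicate 2, 34 without control replicate 3, 26 without deafferented replicate 1 and 0 with the 2 groups fitted alone. Without deafferented replicate 1, Timp1 (adjusted p = 0.197), Atf3 (0.0773) and Cd68 (0.0674) did not pass, nor did Cd68 without control replicate 3 (0.0618). Calls also ended for Inhbb without 5 of the 6 arrays, for C1ql3 without 4 and for Arhgap24 without 3, with adjusted p up to 0.382, 0.356 and 0.171, each without deafferented replicate 3.

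**Figure D4:**
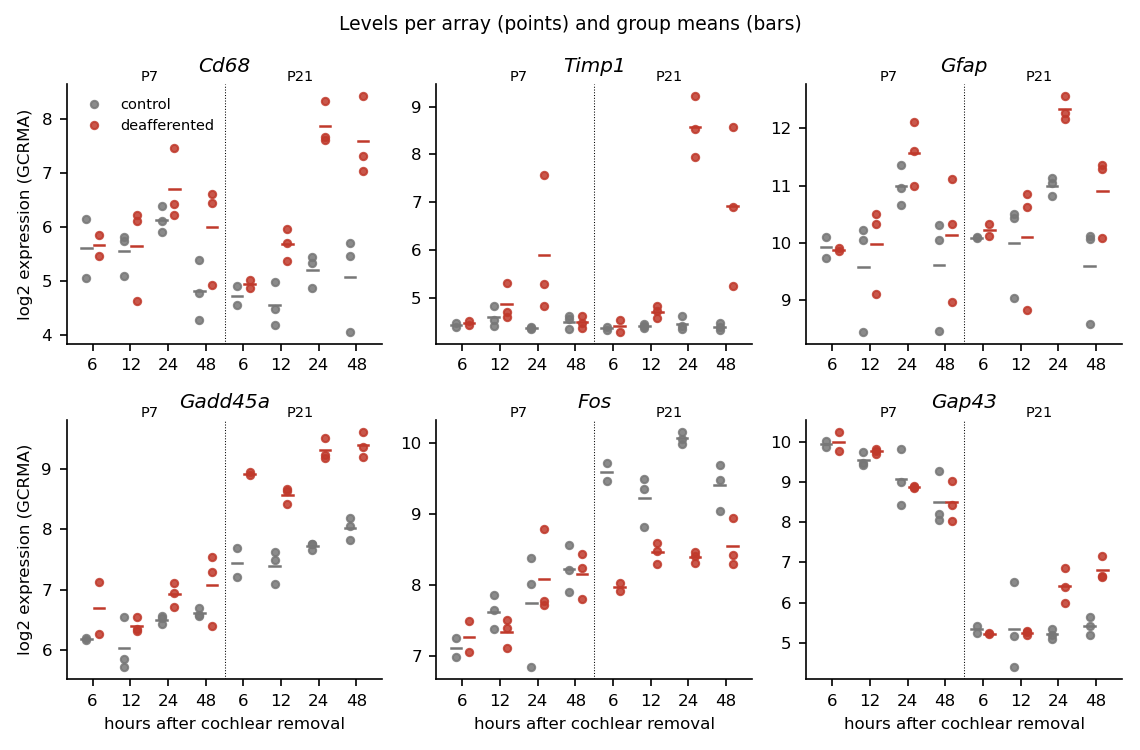
Log2 level of Cd68, Timp1, Gfap, Gadd45a, Fos and Gap43 in each array (points) of the control and deafferented nucleus by age and time, with bars at the group means. At P21 24 h Timp1 lies at 8.57 ± 0.63 (SD, n = 3) on the deafferented side against 4.45 ± 0.14 in the controls, and Fos at 8.39 ± 0.08 against 10.07 ± 0.09.

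Whether the response at P21 changed with time was tested as the mean effect at 24 and 48 h minus that at 6 and 12 h. Injury and immune genes rose more at the later times. Timp1 differed by 3.15 ± 0.514 (limma adjusted p = 0.00285), Atf3 by 1.86 ± 0.309 (adjusted p = 0.00285) and Tgm1 by 1.78 ± 0.219 (adjusted p = 3.22e-05). Mpeg1 differed by 1.74 ± 0.29 (adjusted p = 0.00285) and Capg, an actin-capping protein of macrophages, by 1.65 ± 0.348 (adjusted p = 0.0374). The lists of reactive astrocytes (median 0.68, adjusted p = 2.06e-05), microglia (0.60, adjusted p = 0.000142) and complement (0.42, adjusted p = 0.00138) were shifted upward with an estimated correlation. So were the unfolded protein and integrated stress response (0.12, adjusted p = 0.0108) and axon injury and growth (0.04, mean 0.27, adjusted p = 0.00268). In this contrast 22 probe sets (18 genes) passed, 21 higher and 1 lower, and 51 with the array pair as a block, 45 higher and 6 lower. The count was 12 without each of the 4 arrays of 6 h, 14 without 24 h control replicate 1, 48 h control replicate 1 or 48 h deafferented replicate 1, and 13 without 24 h deafferented replicate 2 or 48 h control replicate 2. With each age fitted alone Atf3 (adjusted p = 0.0841, 5.31e-06 to 0.0841 over its alternatives) and Mpeg1 (0.0903, 1.28e-05 to 0.0903) did not pass. The call of Capg ended without 16 of the 22 arrays, with adjusted p up to 0.139 without 6 h deafferented replicate 1.

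The same comparison at P7, averaged over the 4 times, yielded few calls. Hmox1 rose 1.77-fold (log2 change 0.82 ± 0.151, 11 arrays per side, limma adjusted p = 0.0365, higher in 10 of 11 pairs). Car3, a carbonic anhydrase of muscle and fat, fell by 1.56 ± 0.261 (adjusted p = 0.0154, lower in 10 of 11 pairs). The mean of Car3 on the deafferented side was 4.7 ± 0.44 (SD, n = 11), near the background. Its controls ranged from 4.74 to 9.13, with the highest value at 12 h, so the size of the change rests on uneven control levels. Cd68 differed by 0.48 ± 0.238, Gfap by 0.37 ± 0.292, C1qa by 0.18, Jun by 0.16, Atf3 by 0.11, Fos by 0.04, Gap43 by 0.01, Calb2 by -0.05, Bcl2 by -0.19 and Igf1 by -0.21, and none of these passed (adjusted p = 1 for each). The 2 called probe sets, 1 higher and 1 lower, became 6 with the array pair as a block, 3 higher and 3 lower. Neither gene passed without P7 6 h deafferented replicate 1 (adjusted p = 0.203 for Hmox1 and 0.125 for Car3), nor without the 24 h arrays (0.825 for Hmox1 and 0.113 for Car3, with ranges over alternatives of 0.00222 to 0.825 and 0.000566 to 0.827). In all, the call of Hmox1 ended without 10 of the 22 arrays and that of Car3 without 3. The count was 0 without P7 6 h deafferented replicate 1 or P7 24 h control replicate 1 and 11 without P7 12 h control replicate 2. It was 4 without 12 h deafferented replicate 1 or 24 h deafferented replicate 1 or 2, and 1 without 6 h control replicate 2, 12 h deafferented replicate 2, 24 h control replicate 2, 48 h control replicate 1 or 48 h deafferented replicate 1 or 2.

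Of the gene lists at P7, microglia and macrophages had the strongest shift, with a median of 0.18 and 25 of 29 fitted changes above 0 (camera adjusted p = 2.35e-10, and adjusted p = 0.0555 with an estimated correlation). Of its genes 0 passed over all probe sets (2 when adjusted over the list alone). Cytokines and chemokines rose (median 0.11, 16 genes, adjusted p = 0.00478, and adjusted p = 0.0324 with an estimated correlation). This was the 1 list call of 11 that held with the estimated correlation, although not without the 24 h arrays (adjusted p = 0.223, 0.0017 to 0.223 over its alternatives) or with the array pair as a block as well (0.109). Limma's fry, which tests a list against no change and not against the other genes, gave an adjusted p of 0.129. Without P7 12 h control replicate 3 the number of list calls was 7. Among the 10 calls that were lost were reactive astrocytes (median 0.09, adjusted p = 0.000403, and adjusted p = 0.332 with an estimated correlation) and complement (0.15, adjusted p = 0.0137, and adjusted p = 0.11 with an estimated correlation). Also lost was meninges and choroid plexus (-0.16, adjusted p = 0.00157, and adjusted p = 0.427 with an estimated correlation). With an estimated correlation, the other lost calls were upward for astrocytes (0.05, adjusted p = 0.456), proliferation (0.05, adjusted p = 0.456) and voltage-gated sodium and calcium channels (0.08, adjusted p = 0.427). They were downward for cholesterol synthesis (-0.07, adjusted p = 0.497), the mitochondrial respiratory chain (-0.04, adjusted p = 0.651) and neutrophils (-0.12, adjusted p = 0.398).

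By time at P7, no probe set passed limma's test at 6 h (388 at an unadjusted p under 0.05, 0 with the array pair as a block) or at 48 h (597 at an unadjusted p under 0.05, 1 with the block). Without control replicate 1 the count at 6 h was 14. At 12 h the 3 called probe sets were lower on the deafferented side, Lipf, a gastric lipase (-3.32 ± 0.615), Car3 (-2.67 ± 0.491) and Col2a1, the collagen of cartilage (-2.13 ± 0.397). Each had a limma adjusted p of 0.0316 with n = 3 arrays per side. Each was lower in 3 of 3 pairs, although Lipf in replicate 2 by less than the digits given here, with 1.68 on both sides. Lipf lay at 5.03 ± 2.98 (SD) in the controls and 1.71 ± 0.12 on the deafferented side, at the background of the arrays. The count at 12 h was 8 with the array pair as a block (1 higher and 7 lower), 0 without control replicate 1 or any of the 3 deafferented replicates, 1 without control replicate 3 and 9 without control replicate 2. At 24 h 1585 probe sets had an unadjusted limma p under 0.05, more than at P21 24 h (1028), but only 1 was called. The called probe set belonged to Cd44 (1.82 ± 0.279, adjusted p = 0.00299), and is named here after its values were seen. It is not the brighter probe set of the gene, which differed by 1.18 ± 0.264 (adjusted p = 0.0913). The count at 24 h was 49 without control replicate 1, 278 without control replicate 2, 0 without control replicate 3 and 8 without deafferented replicate 2. With the array pair as a block it was 165 (115 higher and 50 lower). Whether the numbers pair the arrays there stays open: the correlation within a number was 0.417, -0.00178 and 0.0203 for replicates 1, 2 and 3. For the change of the P7 response with time, 0 probe sets passed limma's test (410 at an unadjusted p under 0.05, 0 with the block), and 5 without 12 h control replicate 2. In that contrast the extracellular matrix and protease list had a median of 0.21 (adjusted p = 0.0482 with an estimated correlation). At 48 h the microglia and macrophage list had a median of 0.47 (adjusted p = 1.55e-09, and adjusted p = 0.154 with an estimated correlation). Of the genes followed whatever their values, none passed at any time at P7, with adjusted p = 1 for each at 6, 12 and 48 h and 0.476 or more at 24 h (lowest for Jun, 0.35). Their largest changes of either sign were those of Cd68 at 48 h (1.18 ± 0.448) and Igf1 at 12 h (-0.44 ± 0.194).

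Whether the response differed between the ages was tested directly, as the P21 effect minus the P7 effect. Averaged over the times, the response was more positive at P21 for Lalba (1.23 ± 0.22, limma adjusted p = 0.00507), Tgm1 (0.97 ± 0.155, adjusted p = 0.00184) and Gadd45a (0.96 ± 0.167, adjusted p = 0.00402). The same held for Mapk13 (0.95 ± 0.155, adjusted p = 0.00185) and the tetraspanin Tspan4 (0.43 ± 0.089, adjusted p = 0.0445). It was more negative for Fos (-1.26 ± 0.209, adjusted p = 0.00208), Arhgap24 (-0.99 ± 0.152, adjusted p = 0.00104) and Dusp1 (-0.83 ± 0.122, adjusted p = 0.000628). The reactive astrocyte list was shifted upward by a median of 0.41 over 27 genes (camera adjusted p = 2.17e-17, and adjusted p = 0.00286 with an estimated correlation), with 1 gene called and 10 when adjusted over the list alone. Without the 24 h arrays its median was 0.151 (adjusted p = 3.77e-05, and adjusted p = 0.499 with an estimated correlation). Jun differed by 0.59 ± 0.129 and did not pass (adjusted p = 0.0649), but did with the array pair as a block (adjusted p = 0.0233, 0.00186 to 0.942 over all alternatives). Atf3 differed by 0.92 ± 0.219 (adjusted p = 0.147, 0.00326 to 1 over its alternatives). Cd68 (1.16 ± 0.336, adjusted p = 0.493), Igf1 (0.50 ± 0.145, adjusted p = 0.493) and C1qa (0.46 ± 0.149, adjusted p = 0.807) did not pass. Neither did Gap43 (0.58), Gfap (0.36), Calb2 (-0.14) or Bcl2 (-0.26), each with adjusted p = 1.

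The other 8 list calls of the age difference did not hold with an estimated correlation. With that correlation, adjusted p was 0.0904 for microglia and macrophages (median 0.18, adjusted p = 1.77e-08 with the preset one), 0.0904 for immediate early genes (median -0.04, mean -0.19) and 0.153 for complement (median 0.15). It was 0.392 for meninges and choroid plexus (-0.20) and for endothelium and pericytes (-0.15), 0.542 for cytosolic ribosomal proteins (0.08), and 0.555 for synaptic vesicles and release (-0.11) and for cholesterol synthesis (0.06). In all 12 probe sets (11 genes) passed, 9 higher and 3 lower, or 10 higher and 6 lower after centring each array on its median, and 28 with the array pair as a block, 18 higher and 10 lower. The count rose to 19 without P7 12 h control replicate 2. Without the 24 h arrays it was 3, and Gadd45a (adjusted p = 0.581), Fos (0.0758) and Tspan4 (0.85) did not pass, against lowest values of 0.000139, 1.8e-05 and 0.00285 among their alternatives. Lalba and Tgm1 fell below the filter on dim probe sets without those arrays and had no value. The call of Tspan4 ended without 27 of the 44 arrays.

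By time, the ages differed in 0 probe sets at 6 h by limma (203 at an unadjusted p under 0.05, 0 with the array pair as a block) and in 1 at 12 h. They differed in 22 at 24 h (20 higher and 2 lower, 50 with the block) and 2 at 48 h. At 12 h the gene was Ccl3 (2.39 ± 0.402, adjusted p = 0.0162), which did not pass without 6 of the 12 arrays (adjusted p up to 0.165, without P21 deafferented replicate 2). The count at 12 h was 7 without P7 control replicate 2, 2 without P7 control replicate 3 or P21 deafferented replicate 3, and 0 without P7 deafferented replicate 1 or 2, P21 deafferented replicate 2 or any P21 control replicate. At 24 h, Lalba differed by 3.69 ± 0.415 (adjusted p = 1.96e-06), Tgm1 by 3.26 ± 0.293 (adjusted p = 1.41e-08) and Lgals3 by 2.67 ± 0.545 (adjusted p = 0.023). Socs3 differed by 2.59 ± 0.526 (adjusted p = 0.0225) and Ptx3 by 2.28 ± 0.429 (adjusted p = 0.011). Fos differed by -2.02 ± 0.394 (adjusted p = 0.0176) and Nr4a1 by -1.67 ± 0.363 (adjusted p = 0.0465). The reactive astrocyte list differed at 24 h by a median of 0.90 (adjusted p = 0.0012 with an estimated correlation). At 48 h, Sprr1a differed by 2.17 ± 0.391 (adjusted p = 0.0266) and Mapk13 by 2.03 ± 0.292 (adjusted p = 0.000873), and the microglia list by a median of 0.54 (adjusted p = 0.0123 with an estimated correlation). The 24 h count was 35 without P7 control replicate 2, 14 without P7 deafferented replicate 1, 11 without P7 deafferented replicate 3 and 10 without P21 deafferented replicate 2. Of the 24 h genes, Socs3 and Nr4a1 did not pass without 7 of the 12 arrays (adjusted p up to 0.141 and 0.185), Lgals3 without 6 (up to 0.151), and Ptx3 and Fos without 2 (up to 0.101 and 0.0648). At 48 h Sprr1a did not pass without 6 arrays (up to 0.199, without P21 control replicate 1). It passed without 4 and had no value without the other 2 of the 12, where it fell below the filter. The 48 h count was 4 without P21 deafferented replicate 3 and 1 without P7 control replicate 3, any P7 deafferented replicate, P21 control replicate 1 or 2, or P21 deafferented replicate 1. At 6 h 1 probe set passed without P7 control replicate 1.

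The control nuclei of the 2 ages give the background against which the responses stand, and they differed widely. All lay opposite a removed cochlea. Age can therefore not be told apart here from how the opposite nucleus reacts to surgery at each age. Dao, a D-amino acid oxidase of hindbrain astrocytes, was 52.8-fold higher at P21 than at P7, and Gng13, a G protein subunit, 21.2-fold. Klk6 (3.98 on the log2 scale), Hapln2, Evi2a (3.16), Anln (3.68) and Ppp1r14a (3.26), which oligodendrocytes express, were higher at P21, as were Sln (3.84), Hsd11b1 (3.80) and Car8 (3.29). Dcx, a microtubule protein of young neurons, was 40.7-fold lower at P21 and Gap43 15.5-fold lower. The cell cycle genes Top2a (-4.28), Mki67 (-3.92) and Rrm2 (-3.74) were lower, as were Fxyd7 (-4.38), Aplnr (-4.20), Fxyd6 (-3.86), Nt5dc2 (-3.76) and Grp (-3.55). The largest limma adjusted p among these 20 genes was 1.48e-15. Of the genes followed in every comparison, Fos was higher in P21 controls by 1.90 (adjusted p = 6.32e-13) and Calb2 by 1.24 (adjusted p = 9.14e-12). Lower were Igf1 (-2.20, adjusted p = 1.15e-18), Cd68 (-0.63, adjusted p = 0.0246, and 0.15 without the 24 h arrays, 0.0159 to 0.15 over its alternatives) and Bcl2 (-0.44, adjusted p = 0.00682). Gfap (0.14, adjusted p = 0.706), Atf3 (0.06, adjusted p = 0.775), C1qa (0.04, adjusted p = 0.764) and Jun (-0.17, adjusted p = 0.111, 0.048 to 0.307 over its alternatives) did not pass. In all 8187 of 15323 probe sets (5415 genes) passed, 3605 higher and 4582 lower at P21, a balance that turned to 4340 higher and 3820 lower after centring each array on its median.

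Proliferation was the list with the clearest fall between the control ages, with 30 of 31 genes lower at P21 and a median of -1.54 (camera adjusted p = 1.04e-13, and adjusted p = 0.0212 with an estimated correlation). The glucocorticoid response list rose, with a median of 0.91 and 16 of 19 genes higher (adjusted p = 9.15e-07, and adjusted p = 0.0212 with an estimated correlation), among them Mt1 (1.69) and Tsc22d3 (1.55). These were the 2 of 18 list calls that held with an estimated correlation. Oligodendrocytes and myelin had a median of 1.30 with 19 of 24 genes higher (adjusted p = 2.53e-09, and adjusted p = 0.124 with an estimated correlation). The cytosolic ribosomal proteins had a median of -0.56 with 37 of 40 lower (adjusted p = 2.25e-12, and adjusted p = 0.108 with an estimated correlation). With an estimated correlation, adjusted p was 0.0567 for voltage-gated potassium channels (median 0.63), 0.0601 for calcium-binding proteins of auditory neurons (0.77), astrocytes (0.58) and oligodendrocyte precursors (mean -0.85), and 0.0571 for axon injury and growth (-0.48). It was 0.0927 for the circadian clock (0.72), 0.0957 for heat shock proteins (0.16), 0.108 for the inhibitory synapse (0.50) and immediate early genes (0.18). It was 0.269 for synaptic vesicles and release (0.48), blood (0.47) and interferon response and MHC class I (0.30), 0.31 for the respiratory chain (0.17) and 0.429 for meninges and choroid plexus (-0.45).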

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

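The tests below of the spread at P7, the 24 h arrays, the loss of meninges tissue, uneven carry-over, the replicate 3 arrays and skeletal muscle, and the splits within array pairs for the averages, were chosen only after the results were seen. The test of all carry-over genes at P7 12 h and the counts over the other splits were set before.

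The effect of deafferentation differed between late and early times at P21 by a direct test in 22 probe sets. Among them the log2 difference was 3.15 for Timp1, 1.86 for Atf3, 1.78 for Tgm1, 1.74 for Mpeg1 and 1.65 for Capg. The effect differed between the ages, averaged over times, in 12 probe sets. The P21 minus P7 difference was 1.23 for Lalba, 0.97 for Tgm1, 0.96 for Gadd45a, 0.95 for Mapk13, 0.43 for Tspan4, -1.26 for Fos, -0.99 for Arhgap24 and -0.83 for Dusp1. At 12 h the ages differed in 1 probe set, Ccl3, by 2.39. At 24 h they differed in 22 probe sets, with Lalba at 3.69, Tgm1 at 3.26, Lgals3 at 2.67, Socs3 at 2.59, Ptx3 at 2.28, Fos at -2.02 and Nr4a1 at -1.67. At 48 h they differed in 2 probe sets, Sprr1a by 2.17 and Mapk13 by 2.03. The reactive astrocyte list differed between the ages by a median of 0.41. All of these differences were tested as contrasts in limma. Groups of 2 or 3 arrays were not tested for single outlying arrays.

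The first pattern weighed is the larger shift of the reactive astrocyte list at P21 than at P7. Permuting the age of whole pools within each time gave a two-sided permutation p = 8e-05 for the difference of 0.452 in the list mean. Over all times, changes with time included, the pool differences of that mean varied less at P7 (SD 0.2, 11 pools) than at P21 (SD 0.56). Both values argue against a wider spread of the P7 arrays as the whole reason. The list was picked for its age difference in these same arrays, so the permutation p is not independent of that choice. The age difference of the list mean lay 0.476 above the mean of the astrocyte, oligodendrocyte and synaptic vesicle lists (permutation p = 0.00042), which argues against less meninges and choroid tissue as the whole reason, since that would raise all of these lists alike. The part of the 24 h arrays stays open: without them the mean difference was 0.236, and the adjusted p was 3.77e-05 with the preset correlation and 0.499 with an estimated correlation. A weaker astrocyte response in the younger nucleus may account for what is left, as a hypothesis that these arrays do not test beyond the age groups themselves.

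The second pattern is the lower meninges and choroid plexus list on the deafferented side at P21. At P21 6 and 24 h, which hold none of the replicate 3 arrays that stand apart, its median was -0.535 (adjusted p = 0.00467 with an estimated correlation), which argues against those arrays as the whole reason, although the P21 average without them, on fewer arrays, had a median of -0.354 and an adjusted p of 0.0615 with an estimated correlation (-0.36 and 0.0179 with them). The list mean varied between arrays of one group with an SD of 0.28, the widest of 37 lists, but permuting the sides within each time gave a permutation p = 0.0175 for its change (adjusted p = 0.00437 in limma's fry, which tests against no change), which argues against uneven carry-over of bordering tissue unrelated to the side as the whole reason. Ttr, a choroid plexus gene, ranged from 8.9 to 14.43 between the deafferented arrays of P21 24 h, and 2 of the 22 measured genes of the list are also in another list. A difference in dissection that goes with the side is confounded with it and stays open, as does a real decrease in these tissues after surgery at P21, and neither was tested.

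The third pattern is the higher level of genes grouped as cartilage, airway and gland, and muscle in the P7 12 h controls. It was seen in Col2a1, Lipf and Car3 and then in Ctsk, Lum and Bpifa1. Carry-over of tissue near the cochlea into those control pools is a candidate explanation. The 31 measured genes of these tissues that had not been looked at had a median change of -0.35, with 21 lower on the deafferented side (camera p = 0.0276 with an estimated correlation): the 14 cartilage and bone genes had a median of -0.55 with 13 lower (camera p = 0.000195), while the 11 airway and gland genes, the tissue of Lipf, had a median of -0.35 with 8 lower and did not pass (camera p = 0.0849). The 6 skeletal muscle genes among the 31 went the other way, with a median of 0.349 and 0 lower on the deafferented side. The largest of these rises came from 1 array, deafferented replicate 3, with Myl1 at 6.13, Myh3 at 5.72 and Myh8 at 5.59. In deafferented replicates 1 and 2 these genes lay between 4.2 and 4.76, near background. Skeletal muscle as the source of Car3 is argued against by those 6 genes, none of them higher in the controls, and more loosely by levels. The 15 other muscle genes on the arrays, among them Ckm, Acta1 and Mylpf, had means of at most 5.5 in those controls, near background. Car3 averaged 7.31 ± 0.344 (SE) there, but levels of different probe sets can be compared only roughly. Fat as a source of Car3 was not tested. No biological explanation was tested for this pattern, and the calls of Col2a1, Lipf and Car3 depend on single arrays.

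Other splits of the same arrays were counted for each comparison of at least 3 arrays per group. For 3 arrays against 3 only 10 splits exist, too few for a share under 0.05. The real count and the highest of the other splits were 3 and 2 at P7 12 h, where 1 split of 10 gave as many, and 4 and 1 at P21 12 h (1 of 10). They were 124 and 4 at P21 24 h (1 of 10) and 54 and 0 at P21 48 h (1 of 10). At P7 24 h they were 1 and 363 (4 of 10 splits gave as many), and at P7 48 h 0 and 46 (10 of 10, since every split reaches a count of 0). The split with 363 sets control 1, deafferented 1 and deafferented 3 against the rest, so the P7 24 h arrays hold a structure other than the side, as do those of P7 48 h. Among the splits that part as many pairs, the highest other count was 0 at P7 12 h, P21 12 h and P21 48 h and 4 at P21 24 h.

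Of 100 splits, the P21 average was matched by 1, the real one (124 probe sets, highest other 19), as was the late minus early effect at P21 (22, highest other 4), the P21 list count (13, highest other 12) and the control ages (8187, highest other 4974, and 18 lists, highest other 17). No other split reached these counts, a share under 0.05 that was not adjusted over the comparisons. The other splits still called a median of 5 lists for P21, 4 for P7, 4 for the age difference and 7 for the control ages. List calls with the preset correlation thus also arise from arbitrary groupings of these arrays. The share was under 0.05 as well for the P7 average (2 probe sets, 4 of 100 splits as large, highest other 2) and the P7 lists (11, 2 of 100, highest other 12). Other splits gave as many there, so chance is not excluded. The P7 count of 2 is fragile too: it was 0 without either of 2 single arrays, without the 24 h arrays and with each age fitted alone. In 100 splits that swap the sides within array pairs, 2 reached the P7 count (highest other 2) and 1 the P7 lists (highest other 10), 1 the P21 count (highest other 18) and 4 the P21 lists (highest other 14). For the P7 late minus early effect the real count was 0, which all 100 of 100 splits reach, so they decide nothing there (highest other 165). For the age difference, the share was under 0.05 for the average (12 probe sets, 2 of 100, highest other 1055) and for 24 h (22, 3 of 100, highest other 71). Other splits gave higher counts in both, so these splits alone do not exclude chance. Nor do they for its lists (9, 12 of 100, highest other 14), for 12 h (1 probe set, 7 of 100, highest other 1185) or for 48 h (2, 5 of 100, highest other 1495). The high counts point to a structure of the arrays. At 12 h all counts above 4 came from 8 splits that placed the replicate 3 arrays unevenly. In these, one age held 2 of them on one side and 0 on the other. Apart from the real split with its 2 calls, all counts above 0 at 48 h came from 7 such splits. At 24 h, the real split with 22 aside, all counts above 9 came from 9 such splits, although the replicate 3 arrays of 24 h are not those that stood apart. Keeping pairs together, the highest other counts were 1 for the average, 0 at 12 h, 2 at 24 h and 0 at 48 h.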

How the results depend on the processing

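The alternatives without the replicate 3 arrays, without the 24 h arrays and with block and estimated correlation together were chosen only after the results were seen. Of 5014 recomputed values of called genes and lists, 4523 kept their direction and their side of the threshold, 491 kept the direction but no longer passed, and 0 reversed. Of 2497 recomputed values that were not called, 61 passed. Robust moderation and the mean of a gene's probe sets moved no count by over 1.5 times, and after each scaling the median change of all genes stayed within 0.05 of 0. Genes near background, such as Timp1, Ccl12, Lalba, Tgm1, Ccl3 and Lipf, are limited by their low control level. The cause of each change below was not tested, except where fewer genes or arrays entered the fit.

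Counts that moved by over 1.5 times follow by alternative, as probe sets called. Without the filter on dim probe sets: P7 6 h 1, P7 24 h 40, P21 12 h 1, P7 average 1. With the stricter filter: 0 for P7 12 h, P7 24 h and for the ages at 12 h and at 48 h, P21 12 h 2, P21 late minus early 13, averaged age difference 6. The stricter filter removed 13 named genes, which have no value there: Adcyap1, Bcl2, Capg, Cck, Ccl12, Ccl3, Ecel1, Lalba, Lipf, Mapk13, Ptx3, Sprr1a and Tgm1. Quantile normalisation gave 6 at P7 12 h and 2 at P7 24 h, median centring 1 for the ages at 48 h, and a constant prior 3 at P7 24 h. Array weights gave 1 at P7 12 h, 35 at P7 24 h, 1 at P7 48 h, 69 at P21 6 h, 20 at P21 12 h, 356 at P21 24 h and 109 at P21 48 h. They gave 4 for the P7 average, 517 for the P21 average, 104 for P21 late minus early, 41 for the averaged age difference, and 2, 3, 60 and 4 for the ages at 6, 12, 24 and 48 h. Fitting each age alone gave 0 for P7 12 h and the P7 average, 2 at P21 6 h and 7 for P21 late minus early. A minimum of 1.5-fold left 62 for the P21 average and 3573 for the control ages. One probe set per gene gave 5 at P7 12 h, 5 at P7 24 h, 1 at P21 6 h, 4 for the P7 average, 14 for P21 late minus early and 5056 for the control ages. With only the 2 groups fitted, fewer arrays gave 0 at P7 12 h, P7 24 h, P21 12 h and P21 48 h, 2 at P21 6 h and 61 at P21 24 h.

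With the array pair as a block, counts were 8 at P7 12 h, 165 at P7 24 h, 1 at P7 48 h, 3 at P21 6 h, 249 at P21 24 h and 104 at P21 48 h. They were 6 for the P7 average, 286 for the P21 average, 51 for P21 late minus early, 28 for the averaged age difference and 50 for the ages at 24 h. As a random effect (consensus correlation 0.345) the block gave 10 at P7 12 h, 307 at P7 24 h, 1 at P7 48 h, 7 at P21 6 h, 19 at P21 12 h, 300 at P21 24 h and 103 at P21 48 h. It gave 13 for the P7 average, 307 for the P21 average, 59 for P21 late minus early, 45 for the averaged age difference, and 85 and 5 for the ages at 24 and 48 h. At P7 6 h, P7 24 h and P21 6 h the correlation within a number did not pass the limit set beforehand, so whether the arrays pair there stays open. Without the replicate 3 arrays of 12 and 48 h, counts were 1 at P7 12 h, 53 at P7 24 h, 1 at P21 6 h, 2 at P21 12 h, 196 at P21 24 h, 6 for the P7 average, and 3 and 35 for the ages at 12 and 24 h. Without the 24 h arrays they were 0 for the P7 average, 35 for the P21 average and 3 for the averaged age difference. The filter is set anew on the arrays kept, so Ccl12, Lalba and Tgm1 have no value in averages without the 24 h arrays. The same holds for Lipf without P7 12 h control replicate 1 or 3 or without the replicate 3 arrays, and for Sprr1a and Ecel1 without P21 48 h deafferented replicate 1 or 2.

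List calls with an estimated correlation were 1 at P7, 6 at P21, 1 for the age difference and 2 for the control ages. With fry they were 0, 8, 1 and 31. With block and estimated correlation they were 0 at P7, 6 at P21 and 1 for the age difference, and without the 24 h arrays 3 at P7.

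Leaving out each array in turn gave from 0 to 14 calls at P7 6 h, 0 to 9 at P7 12 h, 0 to 278 at P7 24 h, 1 to 5 at P21 12 h, 60 to 119 at P21 24 h and 26 to 49 at P21 48 h. It gave 0 to 11 for the P7 average, 0 to 5 for P7 late minus early, 12 to 23 for P21 late minus early and 9 to 19 for the averaged age difference. For the ages at 6, 12, 24 and 48 h it gave 0 to 1, 0 to 7, 10 to 35 and 1 to 4, and for lists at P7 7 to 14.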

Other observations

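The test of the P21 genes at P7 was set before its result was seen, and the test of activity-regulated genes was chosen only after.

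The genes of this paragraph belong to no list, were called at P21 averaged over the times, and were chosen after their values were seen. Lpl, a lipase, rose by 1.06 ± 0.112 (limma adjusted p = 2.02e-07), Clec7a, a receptor of macrophages for fungal glucans whose mean level of 4.37 lies near background, by 1.11 ± 0.126 (adjusted p = 6.7e-07), and Gpnmb, a glycoprotein of phagocytes, by 0.66 ± 0.148 (adjusted p = 0.0138). Fabp5, a fatty acid binding protein, rose by 0.43 ± 0.069 (adjusted p = 0.000186) and Grn, the lysosomal progranulin, by 0.32 ± 0.079 (adjusted p = 0.0416). Lower were Tfrc, the transferrin receptor (-0.52 ± 0.08, adjusted p = 0.000105), Elovl5, an enzyme of fatty acid elongation (-0.40 ± 0.066, adjusted p = 0.0003), Fam20c, a kinase of secreted proteins (-0.62 ± 0.074, adjusted p = 1.97e-06), and the kinase Stk24 (-0.61 ± 0.101, adjusted p = 0.000365).

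A hypothesis for the few calls at P7 is that the same genes respond there less. Of 90 genes called at P21 averaged over the times, 74 had a change of the same sign at P7. Their median change at P7 was 0.119 when each gene is turned to its P21 direction (permutation p = 0.00187 for this P7 median alone), against 0.622 at P21. The genes were chosen by their P21 values, which favours large changes at P21, so the gap between the 2 medians is in part fixed by that choice. Of the 53 genes higher at P21, 45 were above 0 at P7, with a median change of 0.178. Of the 37 lower at P21, 29 were below 0, with a median of -0.069. The P7 changes thus went in the direction that the hypothesis predicts, but how much smaller the response is at P7 cannot be read from these medians. The same steps were applied here to both ages, but whether their arrays were normalised together is not given. The ages differ in 8187 probe sets of their controls, and age itself was not separated from what the nucleus contains at each age.

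A hypothesis for the fall of immediate early genes at P21 is lower activity of the deafferented neurons. It predicts that other genes regulated by activity fall with them. The list of activity-regulated secreted and synaptic genes had a median of 0.038 at P21 and did not pass with an estimated correlation (adjusted p = 0.208), so this list does not decide the question.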
